A study of Rattus norvegicus with 6 samples.

How the data were processed

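Small RNA libraries of rat bone marrow mesenchymal stem cells were analysed, 3 of exercise and 3 of control, named by group and the number in their titles. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a TruSeq small RNA kit and sequenced on an Illumina HiSeq, and ACGT101-miR removed adapter dimers, low-complexity reads, repeats and reads of rRNA, tRNA, snRNA and snoRNA families. The same protocol speaks of more libraries than the 6 used here. Per the labels, the running sessions began at 10 m/min on a 0 degree slope for 20 min over the first 3 days and, after 2 days of rest, rose to 20 m/min at 5 degrees for 60 min. The rats were 8 weeks old at the start and numbered 12.

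The deposited table gives, per the file headers, a raw read number per miRNA sequence and library. Because 8.65% of values were not whole (tolerance 1e-06), these were treated as estimated counts, which the authors appear to have divided among several entries, and they were rounded to whole numbers before each count test. The table also holds the authors' normalized signal, which equalled the raw value times 1 constant per library (0.893, 0.556 and 0.780 in exercise, 1.47, 2.13 and 0.926 in control). How the constant was chosen, the aligner, the miRBase release and the genome build are not given in the sources used here. Per the file headers, coordinates are those of precursors, and reads were mapped to miRNAs of rat, then of other species, then to predicted hairpins. Near-identical members of a family, and sequences named after other species, could share reads, and 17 abundant sequences had the same counts as another sequence.

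Of 1309 entries, 132 that repeated another entry's sequence and counts were dropped, which left 1177 sequences. Of these, 447 had a rat name, 399 had the name of another species and 331 were predicted. A further 66 lines were blank and held no entry. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of at least 63.4), so each counted as 1 sample. Depth ran from 1014513 to 3758834 counts, and a count of 0 allows up to 0.798 to 2.96 CPM (3 counts of the total).

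Groups were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg threshold 0.05, 528 sequences kept). CPM values are scaled by TMM, while shares are of all counts. The 20 lists were tested with camera in limma 3.58.1 on log2 CPM, two-sided, with the preset correlation of 0.01, adjusted over the 17 lists with at least 3 tested sequences, and with an estimated correlation beside it. fry, which tests whether a list's sequences move 1 way on balance, gave adjusted p of 0.895 to 0.941. A list's median and its count above or below 0 come from edgeR's fold changes of group means, while camera weighs means of log2 CPM, so a list led by a single library can differ in sign between them. In addition, camera compares a list with all other sequences, so its direction is relative to them. A list said to turn direction can therefore keep its own median above 0. Shares were compared with exact two-sided permutation tests in scipy 1.17.1, whose smallest p here is 0.1, and Wilson intervals are at 95%. Lists, tests and alternatives were fixed before the data were examined. The mesenchymal list stands for the cells the labels name, and the muscle, leukocyte, erythroid, endothelial and platelet, epithelial and liver, neural and cartilage lists for other cell types.

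Named miRNAs are the 10 with the highest mean CPM, those past the threshold with a mean CPM of at least 10 (up to 10 per direction), or, as fewer than 10 passed, the 10 with the smallest unadjusted p at that abundance, and of each list up to 4 members past the threshold or else the 2 most abundant tested members. Predicted sequences were counted and not named. The miR-28-3p sequence and the miRNAs called without the filter were named after their values were seen, as were those in the other observations.

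The scripts were tested on simulated counts with the means, depths and spread of these 528 sequences, 200 of them changed. Each sequence was drawn independently, while the correlation estimated within lists of the real data ran from -0.06 to 0.92. The simulated rates may therefore differ from those in the real data. An adjusted p threshold is also easier to reach when many sequences change. With only a few changed sequences, which was not simulated, recovery would be lower. At an adjusted p of 0.05 edgeR recovered 2.91% of 2-fold, 23.4% of 4-fold, 60.4% of 8-fold and 82.7% of 16-fold changes, and 2.04% of calls were false. With no change edgeR made 0 calls in 20 simulations, with 3.97% at an unadjusted p under 0.05. The biological coefficient of variation was 78.9%.

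Alternatives were other scalings (median-ratio size factors, upper quartile, library totals only), DESeq2 1.42.0, limma-voom, limma on the authors' normalized values with pseudocounts of 1, 0.5 and 5, no filter, a filter of 10 CPM in 3 samples, a replicate block, leaving out each library, summing to mature names, rat names only, leaving out the most abundant miRNA, and an adjusted p of 0.1. DESeq2 was run on all sequences with its own filtering, not on the 528. Leaving out both exercise 3 and control 3, adding miR-1b to the muscle list, and DESeq2 on the 528 sequences were chosen after seeing the data. Scaling by library totals moved the median log2 fold change of all sequences from 0.09 to -0.11, and upper quartile scaling moved it to 0.21.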

Results

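Small RNA was sequenced from bone marrow mesenchymal stem cells, the marrow cells that can form bone, cartilage and fat, taken from the femur and tibia of Sprague-Dawley rats. The exercise group ran on a treadmill once a day on 5 days a week for 8 weeks, and the other group served as control. Each group had 6 rats and gave 3 libraries, and the labels do not say which rats went into which library, so p-values measure only the spread between these samples. The exercise libraries held 2581175, 3758834 and 3670011 counts and the control libraries 1250399, 1014513 and 2605505, in replicate order. A count was present in 482 to 877 of 1177 miRNA sequences per library.

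The most abundant miRNAs were miR-191a-5p, at 148248 ± 112197 CPM in exercise and 144978 ± 71718 in control (mean ± SD, n = 3 per group), and miR-133a-3p, a miRNA of striated muscle, at 122470 ± 147793 and 77400 ± 41456. Next came miR-140-3p of cartilage (81175 ± 57952 and 41987 ± 9182 CPM), miR-486, listed here as erythroid (59375 ± 21080 and 45284 ± 26789), and miR-26a-5p (39171 ± 6349 and 43329 ± 10005). The 10 most abundant also included miR-125b-5p (34392 ± 7233 and 34618 ± 16812 CPM), miR-378a-3p (45633 ± 55045 and 21751 ± 5131), miR-1b (41532 ± 55870 and 23647 ± 23536), miR-486b-5p (30733 ± 12112 and 21379 ± 13836) and miR-30d-5p (26851 ± 5669 and 24601 ± 8429). None of these 10 passed edgeR's test between the groups (adjusted p = 0.999 for each).

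Libraries of the same group were far apart. miR-191a-5p took 20.9% of counts in exercise 1 (95% Wilson interval 20.9 to 21.0) and 1.75% in exercise 3 (1.74 to 1.76), while miR-133a-3p took 3.64% (3.61 to 3.66) and 25.3% (25.2 to 25.3) in the same libraries. Among controls, miR-133a-3p took 5.78% of counts in control 1 (5.74 to 5.82) and 11.8% in control 3 (11.7 to 11.8). These intervals cover counting error only. The first principal component, with 48.6% of the variance, placed exercise 3 at 29.5 and control 3 at 19.4, and the other 4 libraries between -20.3 and -6.97. Spearman correlations within a group ran from 0.709 to 0.897 across miRNAs, which are not independent replicates.

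**Figure D1:**
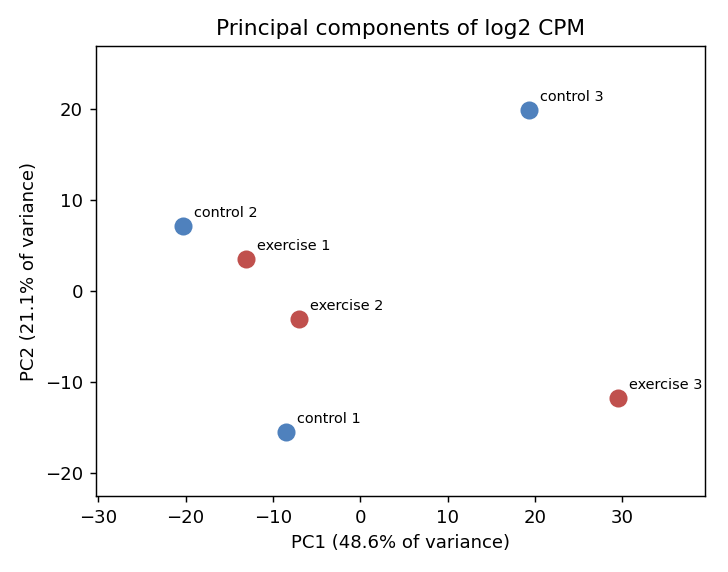
Each point is a library, placed by the first (48.6% of variance) and second (21.1%) principal components of log2 CPM, in red for exercise and blue for control. Exercise 3 (29.5) and control 3 (19.4) lie to the right of the other 4 libraries on the first component, and the groups overlap on both.

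The first comparison asked which miRNAs differed between marrow stem cells of exercised and control rats. miR-1260 averaged 6823 ± 2076 CPM in exercise and 2059 ± 494 in control (mean ± SD, n = 3 per group), a log2 fold change of 1.73 ± 0.45 (SE). It is an 18 nt sequence with a name from another species. miR-455-3p, which comes from the cartilage gene Col27a1, averaged 3618 ± 1944 and 1125 ± 320 CPM (log2 fold change 1.69 ± 0.58). miR-671 averaged 65.1 ± 5.92 and 25.3 ± 2.62 CPM (log2 fold change 1.36 ± 0.50). All 3 had every exercise library above every control library, yet none passed edgeR's quasi-likelihood test (adjusted p = 0.999 for each).

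The other 7 of the 10 miRNAs with the smallest unadjusted p also had an adjusted p of 0.999 by edgeR. mir-5100-p5 (255 ± 51.1 against 70.4 ± 34.7 CPM, log2 fold change 1.85 ± 0.55), miR-2478 (1175 ± 440 against 390 ± 93.4, 1.59 ± 0.49), miR-1386 (738 ± 418 against 209 ± 89.0, 1.82 ± 0.60) and miR-7977 (667 ± 224 against 172 ± 129, 1.96 ± 0.67) also had every exercise library above every control library. Like miR-1260, these were 18 nt sequences with names from other species. The remaining differences rested on 1 or 2 libraries. miR-192-5p, a p53-induced miRNA also abundant in liver, had 177 CPM in exercise 2 and 672 in exercise 3 against 24.7 in exercise 1 (log2 fold change 3.75 ± 1.10, and 2.23 without exercise 3). The erythroid miR-144-3p had 913 CPM in exercise 2 against 98.8 and 16.4 in the other two (3.91 ± 1.37, and 1.36 without exercise 2). The epithelial miR-203a-3p had 6331 CPM in control 3 against 15.1 and 34.6 in the other two controls (-6.11 ± 2.18), and without control 3 its log2 fold change was 0.38. The file places the precursors of miR-192-5p on chromosome 1 (221634971 to 221635082), miR-455-3p on chromosome 5 (79097199 to 79097297), miR-144-3p on chromosome 10 (65291365 to 65291447), miR-203a-3p on chromosome 6 (136704961 to 136705057) and miR-671 on chromosome 4 (7108725 to 7108842), in a genome build not given in the sources used here.

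**Figure D2:**
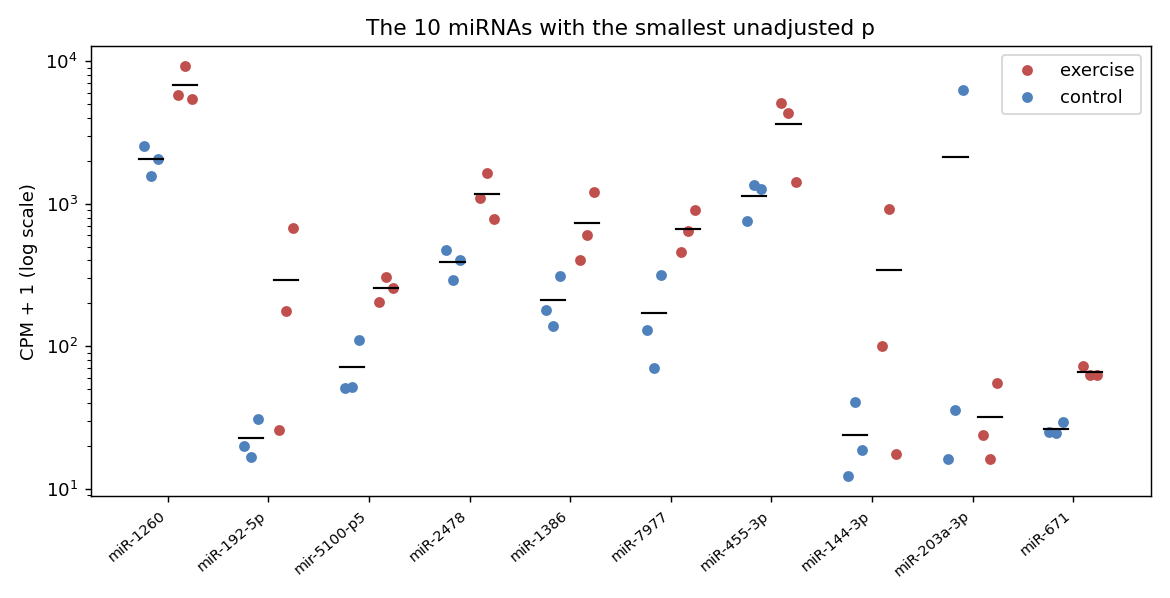
CPM plus 1 on a log scale for the 10 miRNAs with the smallest unadjusted p, with a point per library (exercise red, control blue, 3 each) and a line at the group mean. miR-203a-3p is at 6331 CPM in control 3 alone, and miR-671 is at 61.4 to 71.9 CPM in exercise and 23.7 to 28.3 in control. miR-1260, mir-5100-p5, miR-2478, miR-1386 and miR-7977 are 18 nt sequences with names from other species.

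Over all 528 sequences tested, edgeR called 0 higher and 0 lower at an adjusted p of 0.05, with 17 at an unadjusted p under 0.05, of which 13 were higher and 4 lower in exercise. limma-voom on the same sequences called 0 (11 unadjusted). DESeq2, run without that abundance filter, gave an adjusted p for 1147 sequences and called 0 higher and 1 lower (30 unadjusted), the lower one being a miR-28-3p sequence with 57 counts in control 2 and 0 in the other 5 libraries. On the 528 sequences, a run added after seeing the data, DESeq2 called 0 (20 unadjusted), with an adjusted p for 510 of them and none for miR-203a-3p. edgeR without the abundance filter called 6 higher and 10 lower, among them the same miR-28-3p sequence lower, miR-144-3p and miR-192-5p higher and miR-203a-3p, miR-205 and miR-200c-3p lower. The last 3 had 15638, 120486 and 17352 counts in control 3 and at most 171, 4211 and 1500 in any other library. miR-144-3p had 3619 counts in exercise 2 and at most 232 elsewhere, and miR-192-5p had 700 in exercise 2, 2124 in exercise 3 and at most 74 elsewhere. Libraries of the groups did not overlap for 25 sequences above and 11 below in exercise, or 6.82% where chance gives 10%. The typical sequence had a log2 standard error of 0.77. In simulated data of this design with 200 of the 528 sequences changed, 23.4% of 4-fold changes and 82.7% of 16-fold changes were recovered. Were only a few sequences changed, these rates would be lower. Without exercise 3 and control 3, a comparison chosen after seeing the data, edgeR again called 0, with 65 at an unadjusted p under 0.05.

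The next comparison asked whether miRNAs of a shared role or cell type differed together, over 20 lists. The leukocyte list alone passed: miRNAs of myeloid and lymphoid cells fell in exercise as a list by camera (9 of 13 sequences below 0, median log2 fold change -0.28, adjusted p = 0.0452), with adjusted p = 0.769 with an estimated correlation. Its most abundant members were miR-223-3p, at 3713 ± 2900 CPM in exercise and 5233 ± 3348 in control, and miR-146a-5p, at 2070 ± 724 and 2578 ± 81.8 (n = 3 per group). The list took 0.214% of counts in exercise 3 (95% Wilson interval 0.210 to 0.219) and 1.16% in exercise 1 (1.15 to 1.18). Control 3 was low as well, at 0.601% (0.592 to 0.611) against 1.44% in control 1 (1.42 to 1.46) and 1.36% in control 2 (1.34 to 1.38). Other lists moved with it in exercise 3, where muscle miRNAs took 27.2% of counts (27.1 to 27.2) and the miR-17 clusters 0.960% (0.950 to 0.970), against 4.47% (4.44 to 4.49) and 5.03% (5.00 to 5.06) in exercise 1. The call was lost without control 2 (adjusted p = 0.375), and without exercise 3 the direction turned (adjusted p = 0.688). It was lost as well with library totals only (0.0545), with the stricter filter (0.0867), with sequences summed to mature names (0.0824) and without both exercise 3 and control 3 (0.862).

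miRNAs reported to repress RUNX2, the transcription factor that starts osteoblast formation, had 7 of 9 sequences below 0 (median -0.66, camera adjusted p = 0.098). miR-23a-3p averaged 10139 ± 2094 CPM in exercise and 16105 ± 4523 in control. The list's 9 sequences came from 7 members. Its most abundant member, miR-133a-3p, had a log2 fold change of 0.66 ± 0.87 (SE), and the list's share of counts was 12.5% ± 13.0 in exercise and 11.9% ± 6.15 in control (mean ± SD, n = 3 per group, exact two-sided permutation p = 1), with 4.97% in exercise once exercise 3 was left out. Other miRNAs reported to inhibit osteoblast differentiation had 11 of 17 below 0 (median -0.19, camera adjusted p = 0.166). Among them, miR-30d-5p had a log2 fold change of 0.13 and miR-125b-5p of -0.01. Those reported to promote it had 9 of 13 below 0 (median -0.14, adjusted p = 0.379), with miR-29a-3p at 7015 ± 1873 and 7705 ± 1504 CPM and miR-26a-5p as given above. Mechanosensitive miRNAs had 8 of 13 below 0 (median -0.29, adjusted p = 0.166), with miR-214-3p at 4965 ± 2843 and 6477 ± 1455 CPM and miR-139-5p at 3758 ± 346 and 3520 ± 944. miRNAs reported to promote fat cell formation had 8 of 13 below 0 (median -0.34, camera adjusted p = 0.192). The abundant members miR-378a-3p (log2 fold change 1.07) and miR-30d-5p (0.13) were above 0. The mesenchymal list had 12 of 16 below 0 (median -0.12, adjusted p = 0.379), with miR-99a-5p at 15209 ± 1724 and 17886 ± 12083 CPM. With an estimated correlation each of these adjusted p was 0.769. The RUNX2-targeting list, which holds the miR-205 that was high in control 3, passed without control 1 (0.0322) or control 2 (0.0209), but without control 3 its median on camera's scale was 0.32 (adjusted p = 0.873). The mesenchymal, osteogenesis-inhibiting and mechanosensitive lists passed without control 1 (0.0337 each), and over the libraries left out their adjusted p reached 0.672, 0.608 and 0.564. Without control 3 the mesenchymal list (0.294) and the osteogenesis-promoting list (0.733) turned direction.

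miRNAs of the imprinted Dlk1-Dio3 locus, a large cluster expressed in progenitor cells, had 22 of 23 sequences above 0 with a median log2 fold change of 1.01, and did not pass camera (adjusted p = 0.0772, and 0.769 with an estimated correlation). miR-127-3p averaged 1820 ± 1502 CPM in exercise and 724 ± 156 in control, and miR-434-3p 581 ± 667 and 265 ± 86.5 (n = 3 per group). The list passed without exercise 1 (0.000304) or exercise 2 (0.00035), and turned direction without exercise 3 (0.158), the library with its highest share of counts.

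Growth and stress families did not pass. The let-7 family, which restrains growth, had 8 of 10 sequences below 0 (median -0.04, camera adjusted p = 0.359), with let-7b-5p at 11917 ± 775 CPM in exercise and 12718 ± 3405 in control and let-7i-5p at 9404 ± 3600 and 10168 ± 2191. The proliferation-linked miR-17 clusters had 7 of 14 below 0 (median 0.02, but a negative camera direction, adjusted p = 0.229), with miR-92a-3p at 25397 ± 15801 and 21605 ± 11825 CPM and miR-25-3p at 5984 ± 3130 and 6965 ± 3507. The miR-30 family had 5 of 5 above 0 (median 0.20, adjusted p = 0.510), with miR-30c-5p at 6591 ± 4484 and 5734 ± 2644 CPM. Inflammation-induced miRNAs had 7 of 10 below 0 (median -0.28, adjusted p = 0.359), with miR-146b-5p at 541 ± 233 and 636 ± 143 CPM. p53 and senescence miRNAs had 5 of 10 below 0 (median -0.03, a positive camera direction, adjusted p = 0.511), with miR-22-3p at 3370 ± 1005 and 3127 ± 444 CPM. The collagen-targeting miR-29 family had 2 tested sequences, too few for camera, with miR-29c-3p at 14.3 ± 11.0 and 5.84 ± 3.91 CPM. Each camera p here was 0.769 after adjustment with an estimated correlation. The miR-17 clusters passed lower in exercise without exercise 1 (0.0215), exercise 2 (0.00126) or control 3 (0.0333) and turned direction without exercise 3 (0.158) or control 2 (0.980), and let-7 passed without control 1 (0.0337) but reached 0.934 without control 2. The miR-30 list turned direction without exercise 3 (0.688) or control 1 (0.976). Without control 1 its median on camera's scale was still 0.12, so the turn was only relative to other sequences.

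Markers of other cell types varied more between libraries than between groups. Muscle miRNAs took 12.1% ± 13.1 of counts in exercise and 9.04% ± 3.21 in control (mean ± SD, n = 3 per group, exact two-sided permutation p = 1), with 27.2% in exercise 3 (95% Wilson interval 27.1 to 27.2) and 12.8% in control 3 (12.7 to 12.8). These shares leave out miR-1b, which took a further 9.14% in exercise 3, 4.78% in control 3 and 0.813% to 1.41% in the other libraries. All 6 muscle sequences were above 0 (median 0.46, camera adjusted p = 0.379), with miR-206-3p at 10145 ± 4512 and 8207 ± 1249 CPM, but without exercise 3 the exercise share was 4.52% and the list turned direction (median -0.31 on camera's scale, adjusted p = 0.443). Epithelial and liver miRNAs took 0.209% ± 0.201 of counts in exercise and 2.18% ± 3.61 in control (exact permutation p = 0.8), with 6.35% in control 3 (6.32 to 6.38). Of 11 such sequences 6 were below 0 (median -1.30, but a positive camera direction, adjusted p = 0.511), with miR-205 at 576 ± 655 and 16527 ± 27929 CPM and miR-200c-3p at 382 ± 88.2 and 2507 ± 3912. Without control 3 the control share was 0.0892%, without exercise 3 the exercise share was 0.0936%, and the list turned direction without exercise 3 (0.695), control 1 (0.453) or control 2 (0.581). Cartilage miRNAs took 8.22% ± 5.86 and 4.70% ± 1.49 (exact permutation p = 0.4, 3 of 3 above 0, median 0.95, camera adjusted p = 0.359), and the list passed camera without exercise 3 (0.0430) and turned direction without exercise 1 (0.999). The cartilage share was 11.9% in exercise 1, 11.3% in exercise 2, only 1.46% in exercise 3, and 3.11% to 6.07% in the controls. Erythroid miRNAs took 6.12% ± 0.981 and 5.29% ± 3.31 (exact permutation p = 0.9, 8 of 8 above 0, median 0.49, camera adjusted p = 0.359), with miR-451-5p at 4929 ± 6772 and 1754 ± 1261 CPM, and the list turned direction without exercise 1 (0.999) or control 3 (0.595). Without exercise 1 the erythroid list's median on camera's scale was still 0.03. In exercise 3 the erythroid list took 5.79% of counts and miR-486 alone 5.75%, with miR-451-5p at 142 CPM against 12678 in exercise 2. The share in exercise 3 was thus nearly all miR-486 and need not stand for red cells. In exercise 2 the list took 5.36% and miR-486 3.75%. The muscle, epithelial and liver, cartilage and erythroid lists each had adjusted p = 0.769 by camera with an estimated correlation. Endothelial and neural lists had 2 tested sequences each, with miR-126a-3p at 3562 ± 977 and 3796 ± 2273 CPM, miR-126a-5p at 434 ± 223 and 327 ± 299, miR-128-3p with a log2 fold change of 0.24 ± 0.48 (SE), and miR-9a-5p at 4.43 ± 2.30 and 2.44 ± 3.21. In none of the 20 lists did a member pass, over all sequences or adjusted over the list alone, by edgeR. At an unadjusted p under 0.05 by edgeR there were 6 epithelial and liver sequences, 3 RUNX2-targeting, 2 p53 and 1 each among muscle, erythroid and cartilage. Sequences are not always separate miRNAs: the 11 epithelial and liver sequences came from 8 members, and the 9 RUNX2-targeting ones from 7. miR-205 (unadjusted p = 0.0392), high in control 3, is in both of these lists. miR-192-5p (0.00928) is in the epithelial and liver list and the p53 list.

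**Figure D3:**
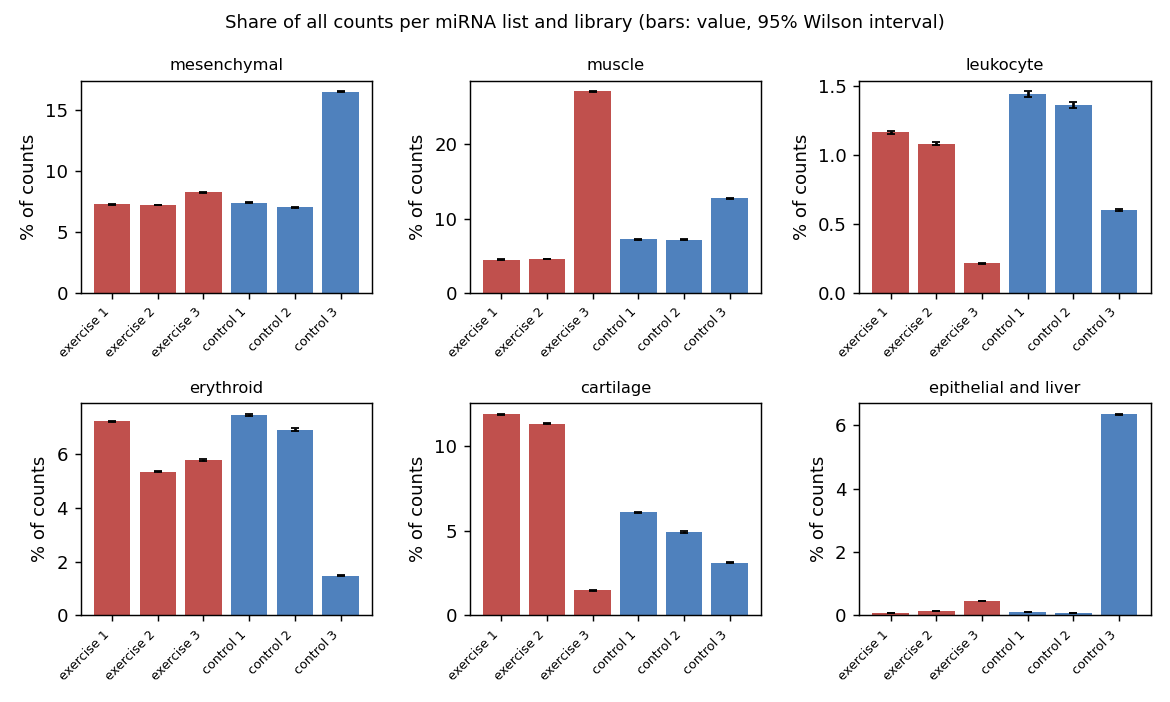
Share of all counts (%) taken by 6 miRNA lists in each library, exercise in red and control in blue, with 95% Wilson intervals. The muscle list is at 27.2% in exercise 3, and the epithelial and liver list is at 6.35% in control 3.

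Shares of counts were also compared for the remaining lists. Exercise lay below control in every library for the mechanosensitive list (1.58% ± 0.121 against 2.02% ± 0.0662), the osteogenesis-promoting list (5.24% ± 1.07 against 6.36% ± 0.294) and the inflammation list (0.316% ± 0.117 against 0.462% ± 0.0380; n = 3 per group, exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 allows). Adjusted over the 20 lists this p was 0.667. Leukocyte miRNAs took 0.819% ± 0.525 and 1.13% ± 0.463 (exact permutation p = 0.5), mesenchymal miRNAs 7.59% ± 0.586 and 10.3% ± 5.39 (p = 0.8), and Dlk1-Dio3 miRNAs 0.260% ± 0.219 and 0.132% ± 0.0410 (p = 0.6), with 0.133% in exercise once exercise 3 was left out. Adipogenesis miRNAs took 9.05% ± 5.13 and 7.98% ± 1.34 (exact permutation p = 1), against the direction of most of their sequences, with 6.09% in exercise once exercise 3 was left out. Osteogenesis-inhibiting miRNAs took 9.14% ± 1.62 and 10.4% ± 2.78 (exact permutation p = 0.6), let-7 4.54% ± 1.07 and 5.25% ± 0.653 (p = 0.4), and the miR-17 clusters 3.67% ± 2.35 and 4.18% ± 2.34 (p = 0.5), with 5.03% in exercise once exercise 3 was left out. The miR-29 family took 0.653% ± 0.120 and 0.819% ± 0.145 (exact permutation p = 0.2), miR-30 4.02% ± 0.962 and 4.03% ± 0.674 (p = 1), and p53 and senescence miRNAs 0.587% ± 0.0370 and 0.668% ± 0.0866 (p = 0.2). Endothelial and platelet miRNAs took 0.378% ± 0.125 and 0.420% ± 0.216 (exact permutation p = 0.8), and neural miRNAs 0.0673% ± 0.00936 and 0.0651% ± 0.0254 (p = 1). The design could not reach 0.05.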

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

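Leaving out both exercise 3 and control 3, adding miR-1b to the muscle list and DESeq2 on the 528 sequences were chosen only after the results were seen. The count past an adjusted p of 0.05 stayed at 0 higher and 0 lower except without the abundance filter, by DESeq2 (1 lower, and 0 on the 528 sequences) and by edgeR (6 higher, 10 lower), where the rat-named miR-429 sequence had 238 counts in control 3 and 0 in the other 5 libraries, and counts at an unadjusted p under 0.05 ran from 6 (rat names only) to 65 (without both exercise 3 and control 3). With no filter, miR-203a-3p, miR-144-3p and miR-192-5p passed (-6.15, 3.97 and 3.73). With limma-voom these were -2.69, 2.65 and 2.72, and with the replicate block miR-203a-3p was at -2.00. With 1 library left out, miR-144-3p ran from 1.36 to 4.59 and miR-192-5p from 2.23 to 4.27. miR-203a-3p ran from -6.80 to 0.38, the latter without control 3. The labels do not say that replicate numbers pair the samples, and 3 libraries per group are too few to decide it. Correlations of deviations were -0.01, 0.30 and 0.44 for numbers 1 to 3. Only number 3 had its best partner in both directions, so something shared by exercise 3 and control 3 stays open. With the replicate block edgeR called 0, with 11 at an unadjusted p under 0.05, and the RUNX2-targeting and Dlk1-Dio3 lists passed camera (adjusted p = 0.0478 each). The leukocyte list lost its call with an estimated correlation (0.769), fry (0.895), library totals (0.0545), the 10 CPM filter (0.0867), summed names (0.0824) and without both exercise 3 and control 3 (0.862), and the p53 list turned direction with the 10 CPM filter (0.963). On camera's scale the p53 list then had a mean of 0.33 and a median of -0.12. Without both 6 lists turned direction, namely mesenchymal (0.352), osteogenesis-promoting (0.857), muscle (0.599), let-7 (0.971), miR-17 clusters (0.971) and Dlk1-Dio3 (0.599). Leaving out each library in turn, adjusted p ran from 0.000304 to 0.375 for Dlk1-Dio3, 0.0209 to 0.873 for RUNX2-targeting, 0.00035 to 0.688 for leukocyte, 0.00126 to 0.980 for miR-17 clusters, 0.0430 to 0.999 for cartilage, 0.0337 to 0.672 for mesenchymal, 0.0337 to 0.608 for osteogenesis-inhibiting, 0.0337 to 0.564 for mechanosensitive, 0.0337 to 0.934 for let-7, 0.122 to 0.790 for osteogenesis-promoting, 0.135 to 0.762 for muscle, 0.131 to 0.999 for erythroid, 0.108 to 0.695 for epithelial and liver and 0.327 to 0.976 for miR-30. Over all list alternatives, direction turned in 22 and 195 kept direction and side. With miR-191a-5p left out of the total, which raises every other share by construction, mean shares moved by over 1 SD for the mesenchymal (8.90%), mechanosensitive (1.88%), erythroid (7.26%), neural (0.0803%) and p53 (0.690%) lists in exercise and the osteogenesis-promoting (7.56%), adipogenesis (9.42%), mechanosensitive (2.41%), let-7 (6.28%), miR-29 (0.970%), miR-30 (4.76%), inflammation (0.549%) and p53 (0.794%) lists in control. The other 189 share values moved by less, which for 1 of 3 libraries left out is fixed by the arithmetic. The cause of the remaining changes was not tested. With the depth and spread here and 200 of the 528 sequences changed, a 2-fold change was recovered in 2.91% of simulated cases.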

Other observations

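Apart from the count of lists in other splits, the tests in this part were chosen after the result was seen. Short sequences of 19 nt or less that end in CCA, the last bases of every mature tRNA, and that carry miRNA names from other species are a set noticed among the smallest p values. The 10 such sequences, among them miR-1260, mir-5100-p5, miR-2478, miR-1386 and miR-7977, had log2 fold changes from 0.76 to 1.96 (median 1.63), and 7 had every exercise library above every control library. They took 1.07% ± 0.393 of counts in exercise and 0.383% ± 0.139 in control (mean ± SD, n = 3 per group). Because the set was picked from these data, no p-value is given for it. Liver-type miRNAs varied by library too: miR-122-5p had 1277 counts in exercise 2, 723 in exercise 3, 68 in control 3 and 5 or fewer in the other 3 libraries.

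A candidate explanation for the short sequences ending in CCA is a difference in insert length. The other 61 short sequences with no rat name had a median log2 fold change of -0.12 (SD 0.98), which argues against a rise of all short sequences alike. They are what remained once the noticed set was taken out. Without both exercise 3 and control 3 they differed from other sequences as a set (camera unadjusted p = 0.00244, direction not recorded), so a part for insert length stays open. tRNA fragments of every length left after the authors' filter would raise longer sequences ending in CCA as well. The 4 of these of 20 nt or more had a median of 0.37 (SD 0.95), too few and too spread to decide. An effect of running itself stays open, as untested.

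Muscle miRNAs were high in exercise 3 and control 3. RNA of striated muscle in exercise 3 may account for it there: the 6 sequences of the muscle list had a median log2 ratio of 1.36 over the mean of the 4 libraries outside this pair, with miR-133a-3p at 2.39, miR-499-5p at 2.01 and miR-206-3p at 0.60, and miR-1b, outside the list, at 3.18. In control 3 the median was -0.37, because miR-133a-3p (1.29) and miR-133b-3p (1.10), and outside the list miR-1b (2.25), were up while miR-499-5p (-1.09) and miR-206-3p (-0.37) were not, and a muscle source there stays undecided. Treadmill running as a shared source is argued against by exercise 1 and exercise 2, whose muscle shares (4.47% and 4.57%) lay below all 3 controls (7.21%, 7.16% and 12.8%), the larger being 0.637 times the smallest control share, and control 3 came from the group that was not assigned to running. How marrow was cleared of muscle is not given in the sources used here.

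Epithelial miRNAs were high in control 3. Epithelial RNA in that library is a candidate explanation: 9 of 13 epithelial sequences were more than 4-fold above the mean of the other 5 libraries, with miR-205 at 46243 against at most 1147 CPM (of all counts) and miR-203a-3p at 6002 against at most 46.6, but 4 were not: miR-141-3p (6.52 against 39.0), miR-375-3p (34.2 against 169) and 2 miR-429 sequences named after other species, with 0 counts in control 3 and 43 and 97 elsewhere. The 9 were not all separate miRNAs. Several were miR-205 sequences, among them 2 with the same counts (1949 in control 3 and 37 in the other 5 libraries). Of the 9, miR-200a-3p was at 382 CPM against 460 in the highest other library, so this remains undecided. Fewer mesenchymal cells in control 3 would raise markers of all other types alike, yet its erythroid share was 0.205 and its leukocyte share 0.429 times the mean of control 1 and control 2, and its mesenchymal share was 2.29 times theirs. Beyond this change in cell make-up, no biological explanation was tested for this library.

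The 10 splits of the 6 libraries are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 17 sequences and the highest other 67, and 7 splits gave at least 17. For camera the real split gave 1 list and the highest other 10, and all 10 splits gave at least 1. Splits with exercise 3 and control 3 on the same side gave 30 to 67 sequences. Splits with them on opposite sides, the real split included, gave 7 to 27. For lists the ranges overlapped, at 6 to 9 with them on the same side and 1 to 10 on opposite sides. The cause of these differences was not tested.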
